A study of Mus musculus with 2 samples.

How the data were processed

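RRBS libraries of mouse hippocampus were available as 1 deposited table that compares 2 libraries, from offspring of choline-supplemented dams and of dams on the normal diet. Groups were taken from the source names of the labels and columns were matched to libraries by the code in the sample titles. Per the labels' protocols, 500 ng of DNA was cut with MspI, inserts of 40 to 220 bp were selected in 2 gel fractions, and the DNA was bisulfite-treated in 2 rounds and sequenced on a HiSeq 2000. Per the series' design text, reads were trimmed with cutadapt and aligned to converted genomes with SOAPaligner 2.21, allowing up to 5 mismatches, with conversion of non-CpG cytosines above 99%, and CASAVA 1.8 is named in the submitters' processing notes. The region caller, its thresholds and the test are not given in the sources used here. The libraries carried no stated molecular identifiers, so all intervals cover counting error only.

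The deposited methylation fraction of a region is, per the file headers and values, the share of methylated among all CpG calls in the region. The deposited coverage (signal) is the mean depth per CpG, and the deposited number of CpG sites completes each row. Multiplying these values gave whole numbers of methylated and total calls in both libraries for 259 of 276 regions (tolerance 1e-06). Calls were used for intervals and tests in those regions only, while the other 17 are given with levels and the authors' p. The deposited p-values equalled a two-sided Fisher's exact test of the calls, within 1%, in all 259 regions. That test takes each CpG call as independent, although calls on the same read are not. The deposited FDR p-values fitted a Benjamini-Hochberg adjustment over 365 p-values (a whole-number rank for 83.3% of regions), of which the largest, 0.0485, was left unadjusted. The adjustment was therefore made over regions that had already passed, and 89 of the 365 were not analysed here. It does not control the error rate over all regions tested, a number not given in the sources used here. An adjustment of the same tests over listed regions adds nothing, and left all 179 regions with whole calls and a depth of at least 10 below 0.05.

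The table's 725 lines repeat each region for every gene element it touches, and 160 lines are exact copies, so regions were counted once each. In the 136 promoter lines many symbols had lost letters: all those altered lacked the letters n, a, m, e, D and I. They were restored in 70 lines from the other lines of the same region, with no line unresolved. Of 296 symbols, 275 were current in the GRCm38 gene table, 19 matched as older names and 2 matched none. The design text names mm10, while the processing notes name mm9 and mm10. The coordinates are not those of GRCm38 (mm10): of 300 pairs of a region and its gene, 27 lay within 3000 bp of that gene, and the farthest region on chromosome 7 ended at 148524799, beyond the chromosome's length of 145441459. Positions are therefore printed as deposited, without a build and without reference sequence, and the deposited annotation was used throughout. Promoter lines span 1 kb on each side of a start, and 19 regions within that distance of a start that the upstream lines give, Crebbp among them, had no promoter line.

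Differences are choline minus control in percentage points. With 1 library per group no test of the diets was made. Shares of regions were given with exact Clopper-Pearson 95% intervals, and direction was compared between element classes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. The size of the difference was summarised over regions with a mean depth of at least 10 in both libraries. The sum of calls over the 259 regions was 86235 in the control and 60988 in the choline library. The median number of calls per region was 219 and 147, and 8 and 81 of the 276 regions had a depth below 10. Fixed before the data were examined were the gene lists and the rule for the genes named: Nr3c1 and Crebbp, the 10 regions with the largest difference in each direction, the 5 genes with most regions (4 genes had at least 3 and the next place was shared by 13, counted by current symbol), and up to 4 genes with a region per list, in order of absolute difference. Gnas, Ldb3 and the genes of the other observations fall outside this rule. As alternatives, the p threshold, the minimum difference, CpG number, depth, promoter definition, chromosomes and merging of neighbours were varied. Added after the data were seen were a depth minimum of 10 for all results, whole calls alone, and Fisher's exact tests with reads as the unit, in which the mean depth, or 2 times the mean depth, stood for the number of reads. The first treats each read as covering every CpG of a region and is the most conservative of the counts used here, and the calls are the most liberal. Without stated molecular identifiers the number of independent molecules is not known and may be smaller.

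The code was tested on simulated data. With 20-point differences placed in 120 of the 276 regions and independent calls, 82.5% were recovered, all in the right direction, and 1.28% of unchanged regions were called. Every region started from the same level there, so these rates check the code and do not give the power in the real data. With no difference and each read in a single state over all CpGs, the test on calls gave p below 0.05 in 50.6% of simulated regions and the test on reads in 2.29% (100 draws). Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.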

Results

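Hippocampal DNA from mouse offspring was examined in 2 libraries by reduced representation bisulfite sequencing (RRBS), which reads cytosine methylation in fragments cut by the enzyme MspI and so samples CpG-rich parts of the genome. The choline library came from offspring of dams given feed with 5 g/kg choline chloride from embryonic day 9 until birth, and the control library from offspring of dams on feed with 1.1 g/kg. Choline is a dietary source of methyl groups, and the title of the series states an interest in mood across generations and in Nr3c1, the glucocorticoid receptor gene. Each group had 1 library, so there were no replicates, and the labels do not say how many animals a library held. No spread between animals could be measured, and every p-value below compares the 2 libraries and not the diets. The deposited table held 276 distinct regions assigned to 296 gene symbols. The regions had a median length of 147 bp (range 9 to 353) and a median of 9 CpG sites (range 5 to 77). The median of the mean CpG depth per region was 24.5 in the control library (range 4.89 to 64.3) and 15.6 in the choline library (range 4 to 64.4), and 218 of the 276 regions were deeper in the control library.

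Methylation differed in both directions, and most listed regions were more methylated in the choline library. Of the 276 regions, 203 were higher and 73 were lower in the choline library, a share of 73.6% higher (exact Clopper-Pearson 95% interval over regions 67.9 to 78.7). Where the choline library was higher, the median level was 11.3% in the control and 23.3% in the choline library. Where it was lower, the medians were 27.1% and 13.8%. Over the 192 regions with a mean depth of at least 10 in both libraries, the median size of the difference was 12.5 percentage points (quartiles 10.7 and 16.2), and 17 regions differed by at least 20 points, of which 11 were higher and 6 lower in the choline library. No listed region differed by less than 10 points or by less than 1.5 times, so the smaller differences between these libraries are not described here. The share higher was 67.7% (130 of 192 regions) at a depth of at least 10 in both libraries and 86.9% (73 of 84) where either depth was below 10. With reads instead of CpG calls as the unit of Fisher's exact test, an alternative added after the data were seen, 2 of the 276 regions had a p below 0.05. Data were also simulated with no difference and every read in 1 state over all CpG sites of its region. There the test on reads gave a p below 0.05 in 2.29% of regions, a larger share than 2 of 276. The real test used region averages and not reads in a single state, so its rate without a difference may be another. The comparison therefore does not tell whether the listed differences are chance. In the same simulated data 33.1% of regions met the criteria seen in the list.

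**Figure D1:**
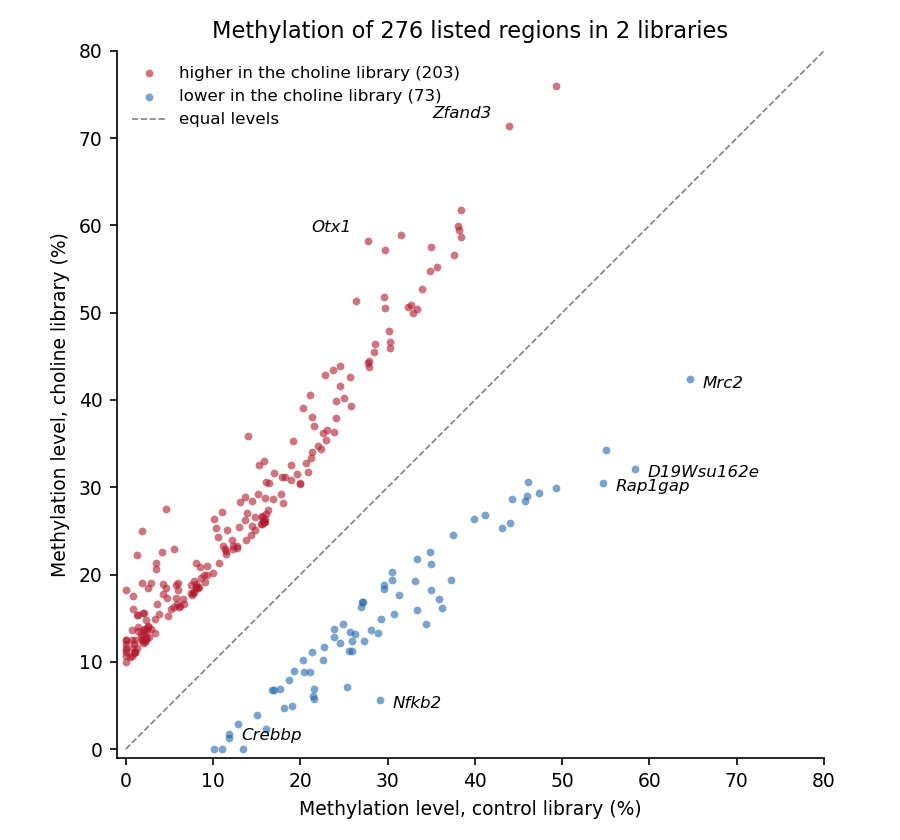
Methylation level of each of the 276 listed regions in the control library (x axis, %) and in the choline library (y axis, %). Each point is 1 region, coloured by direction; the dashed line marks equal levels, and the empty band along it reflects that no listed region differed by less than 10 points.

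The 10 regions with the largest gains in the choline library differed by 22.6 to 30.5 points. An intron of Otx1, a homeobox factor of forebrain development (chromosome 11, 21900555 to 21900736), was methylated at 27.8% of 335 calls in the control and 58.2% of 91 calls in the choline library, a difference of 30.5 points. Fisher's exact p was 1.18e-07 on calls and 0.0684 with reads as the unit. Around the start of Aldh1l1, a folate enzyme used as an astrocyte marker (chromosome 6, 90500745 to 90500876), the levels were 31.5% and 58.9% at equal depths of 14.6. An intron of Cux2, a homeobox factor of upper-layer cortical neurons, stood at 35.0% and 57.6% (chromosome 5, 122492985 to 122493055) and had a p below 0.05 when reads were the unit (Fisher's exact p = 0.0393). The other such region lay in an intron of Ldb3 (Fisher's exact p = 0.0439), which was named after its values were seen. Neither passed Benjamini-Hochberg adjustment over the 276 regions. Further regions among the 10 largest gains were at Zfand3 (27.5 points), Tspan9 (27.4), Magel2 (24.9), Blcap and Nnat (23.3), Ptplad1, now named Hacd3 (23.1), and Tead3 with Tulp1 (22.9). Depth in the choline library was 6.5 at Magel2, 5.78 at Ptplad1, 5.10 at Tead3 with Tulp1 and 8.08 at Tspan9.

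The 10 regions with the largest losses in the choline library differed by 18.2 to 26.2 points, and 7 of them were annotated as intron alone. An intron of Rap1gap, a GTPase-activating protein for Rap1 (chromosome 4, 137279712 to 137279878), was methylated at 54.7% of 508 calls in the control and 30.5% of 213 calls in the choline library (Fisher's exact p = 3.08e-09). An intron of Mrc2, a member of the mannose receptor family (chromosome 11, 105172814 to 105173031), stood at 64.6% and 42.3% at similar depths of 27.9 and 26.1 (Fisher's exact p = 2.94e-10). The start of Nfkb2, a subunit of NF-kappa-B (chromosome 19, 46380292 to 46380422), stood at 29.2% of 48 calls and 5.68% of 88 calls (Fisher's exact p = 4.04e-04). These p-values are on calls. With reads as the unit Fisher's exact p was 0.205 at Rap1gap, 0.172 at Mrc2 and 0.116 at Nfkb2. An intron and promoter region of Gal3st1, which makes the myelin lipid sulfatide, stood at 34.4% and 14.3%. The others were D19Wsu162e, now named Wbp1l (a loss of 26.2 points), Gmpr (20.7), Rps6ka1 (20.1), Mrc1 (19.4), Stap2 (18.7) and Ptprs (18.2).

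Both genes that the labels name for separate bisulfite sequencing of their promoters were looked up. Nr3c1 had no region among the 276 listed. Crebbp, the acetyltransferase that acts as a CREB coactivator, had 1 region over its 5' UTR and upstream sequence (chromosome 16, 4213270 to 4213426, 7 CpG sites). It was methylated in 13 of 110 calls in the control library, or 11.8% (exact 95% interval 6.45 to 19.4), and in 1 of 56 calls in the choline library, or 1.79% (0.0452 to 9.55), a difference of -10.0 points. Fisher's exact p on the calls was 0.0360, the adjusted value in the authors' deposited table was 0.0371, and the choline depth of 8 lay below the coverage minimum of 10. With reads as the unit Fisher's exact p was 0.536, so a difference at Crebbp was not detectable at this depth when reads were counted.

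**Figure D2:**
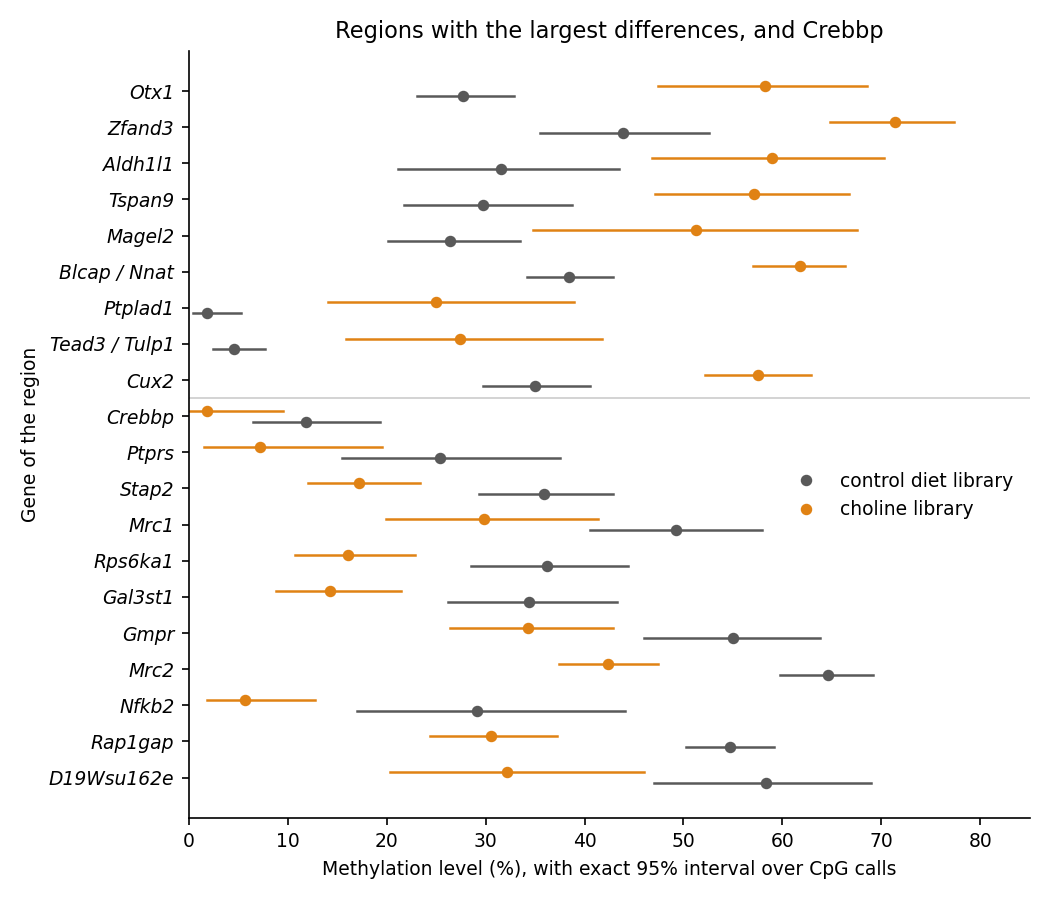
Methylation level (x axis, %) in the control library (grey) and the choline library (orange) of 9 of the 10 regions with the largest gains, the 10 with the largest losses and Crebbp, with exact Clopper-Pearson 95% intervals over CpG calls as lines. At Crebbp the intervals of the libraries overlap (6.45 to 19.4% and 0.0452 to 9.55%), and the grey horizontal line separates gains from losses. The intervals take each CpG call as independent, although calls on the same read are not.

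The next comparison asked which elements of genes the regions touched and whether the direction depended on the element. Introns were touched by 160 regions, coding sequence by 106, promoters (within 1 kb of a transcription start) by 96, upstream sequence (2 kb) by 67, 5' UTRs by 41, downstream sequence by 22 and 3' UTRs by 16, and 147 regions touched at least 2 classes. Coding regions were higher in the choline library in 86 of 106 cases (81.1%, exact 95% interval 72.4 to 88.1), against 117 of 170 other regions (68.8%). Promoter regions were higher in 75 of 96 cases (78.1%, 68.5 to 85.9) and intron regions in 112 of 160 (70.0%, 62.3 to 77.0). In 7 two-sided Fisher's exact tests over regions the smallest p was 0.0254, for coding sequence, with a Benjamini-Hochberg adjusted value of 0.178, so no class differed from the remaining regions in direction after adjustment. Regions are not replicates, and no set of all covered regions was used here, so no enrichment of any class was tested.

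**Figure D3:**
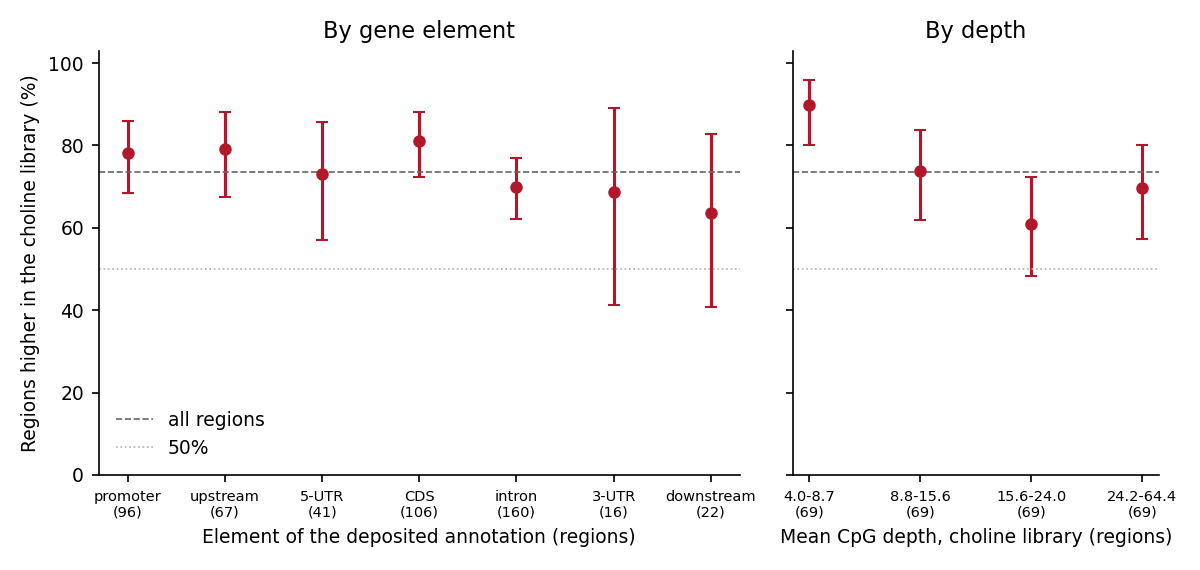
Share of regions higher in the choline library (y axis, %) by element of the deposited annotation (left) and by mean CpG depth in the choline library, in groups of 69 regions (right), with exact Clopper-Pearson 95% intervals over regions; numbers of regions stand in brackets. The share is 89.9% in the 69 shallowest regions and 69.6% in the 69 deepest, and the dashed line marks all regions at 73.6%.

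In the 17 gene lists fixed before the data were examined, 34 genes had a listed region, in 35 distinct regions of which 25 were higher and 10 lower in the choline library. Only 22 of these regions had a depth of at least 10 in both libraries, and with reads as the unit none of the 34 genes kept a region with a p below 0.05. Among 59 genes of synaptic scaffolds and adhesion, 9 had 10 regions, 6 higher and 4 lower. Celsr1, a cadherin of planar cell polarity, was higher by 21.8 points and Bsn, a scaffold of the presynaptic active zone, by 18.2 points, while Ptprs and Cdh23 had differences of -18.2 and -17.3 points. Among 60 imprinted genes, 5 had 4 regions, 3 higher and 1 lower. Magel2 stood at 26.4% and 51.3%, Nnat together with Blcap at 38.5% and 61.7% and Plagl1, a zinc finger factor, at 38.4% and 58.6% in the control and choline library. Gnas, a G protein subunit gene named here after its values were seen, stood at 41.2% and 26.8%. Among 141 homeobox and patterning genes, 9 had 8 regions, 6 higher and 2 lower, among them Otx1, Pax6 (15.4 points) and Lhx2, whose regions differed by 13.2 and -11.0 points, and Meis1 (-13.0 points).

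In the lists on acetylation and choline metabolism, Crebbp, Kat2a, Gnmt and Pld1 had listed regions. Of 23 CREB coactivators and histone acetylation genes, Crebbp and Kat2a, another acetyltransferase, had a region, with differences of -10.0 and 10.5 points. Of 49 genes of choline and one-carbon metabolism, Gnmt, which uses S-adenosylmethionine to methylate glycine, was higher by 11.1 points and Pld1, which releases choline from phosphatidylcholine, had a difference of -13.7 points at a choline depth of 8.60. Of 54 voltage-gated ion channels, the calcium channel genes Cacna1g (13.9 points) and Cacna1a (11.7 and 10.9 points) had regions, each at a choline depth below 10. Gdnf, a neurotrophic factor, was the single member with a region among 48 neurotrophin, plasticity and immediate early genes (10.1 points). No listed region lay at the 29 genes of DNA methylation and its readers, the 38 of monoamine signalling, the 46 glutamate and GABA receptor genes or the 58 clustered protocadherins. Of the marker lists, neuron markers had regions at Rbfox3 (17.2 points) and Calb2 (17.1 points) and astrocyte markers at Aldh1l1, and there were none at markers of oligodendrocytes, of microglia and blood cells, or of endothelium, choroid plexus and meninges. For a gene without a listed region the coverage is not known here, and no list was tested against a background.

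Several genes held more than 1 region. Mn1, a transcriptional coactivator, had 4 regions, 3 higher and 1 lower, and Bcor, a corepressor on chromosome X, also had 3 higher and 1 lower. Cux2 and Fignl2 had 3 regions each, all higher. In the coding sequence of Fignl2, an AAA ATPase (chromosome 15, 100883248 to 100883477, 74 CpG sites), the levels were 18.0% and 28.2%, with the smallest p in the authors' deposited table, 4.64e-26. With reads as the unit Fisher's exact p at this region was 0.343. Counted by current symbol, a further 13 genes had 2 regions, and 9 of the 17 genes with at least 2 regions had both directions. Dbn1 and Prr7 shared the same regions, as did Trove2 and Uchl5. Regions lay on 20 chromosomes, with 269 on the autosomes and 7 on chromosome X. On 18 of the 20 chromosomes more regions were higher than lower in the choline library. The exceptions were chromosome 13 (2 of 6 higher) and chromosome 14 (3 of 6), and the exact 95% intervals at both included the share for all autosomes, 74.0%.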

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

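The share of regions higher in the choline library stayed above 50% under every alternative run, and the alternatives with reads or 2 reads as the unit, a depth of 10, whole calls and no coverage minimum were chosen after the data were seen. From 73.6% it moved outside its interval to 79.8% with at least 10 CpG sites (129 regions), 67.7% at a depth of at least 10 (192 regions) and 65.6% at a depth of at least 20 in both libraries (90 regions), and it was 72.0% among the 25 regions that differed by at least 20 points. The single region above 30 points (1 region, 100% higher) was Otx1. The number of regions depends on the unit of counting: of 276, 35 had a p below 0.05 with 2 reads per unit of depth (71.4% higher) and 2 with 1 read (100% higher), and none passed Benjamini-Hochberg adjustment over the 276 in either. The unit of reads divides the calls by the number of CpG sites, so fewer regions follow from its construction. For the other moved values the cause was not tested. The median size of the difference, 12.5 points, was 11.8 with at least 10 CpG sites and 13.97 as a length-weighted mean. The share higher among promoter regions moved from 78.1% to 66.7% for differences of at least 20 points, where 6 regions remain. Of the 34 listed genes with a region, 11 had a promoter region, 8 a difference of at least 20 points, 21 a depth of at least 10 and 0 a p below 0.05 with reads as the unit. Chromosomes with more regions higher than lower fell from 18 to 10 at 20 points. A promoter reaching 5 kb upstream was not run, because the deposited upstream lines end at 2 kb, and no library could be left out with 1 per group.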

Other observations

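Beyond the named genes, several regions with the smallest p-values in the authors' deposited table lay in coding sequence dense in CpG sites. Those p-values count every CpG call, so many CpG sites lower them by construction. With reads as the unit Fisher's exact p was 0.289 at Sipa1, 0.506 at Rbmxl2 and 0.231 at Oprd1. Sipa1, a GTPase-activating protein for Rap, stood at 17.9% in the control and 31.1% in the choline library over 50 CpG sites, Rbmxl2, a germline RNA-binding protein, at 23.0% and 36.5% over 77 sites, and Oprd1, the delta opioid receptor, at 38.0% and 59.9% over 32 sites. Rpl31, a ribosomal protein gene, stood at 148 of 984 calls and 31 of 790 calls around its start, and a region at Pcsk1n and Eras on chromosome X at 47.3% and 29.3%. In Ldb3, an intron stood at 1.27% of 158 calls and 22.2% of 45 calls. These genes were chosen after their values were seen.

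More regions were higher than lower in the choline library, and this held for 94.2% of the 69 regions with the lowest pooled level and 89.9% of the 69 regions with the lowest choline depth. The excess was not confined to listed regions with uneven depth or low levels. A subset of 83 regions had similar depth (ratio of 2/3 to 3/2) and a pooled level of at least 20%. There 67.5% were higher (exact 95% interval 56.3 to 77.4), against 76.2% of the other 193. In simulated data with no difference, at the real depths and pooled levels and with every read in 1 state, 51.1% of the regions that met the listing criteria were higher in the choline library. The simulation drew only the listed regions, at pooled levels that include their observed differences. It therefore cannot show which direction sampling would favour among all regions covered. The test in regions of similar depth was chosen after the data were seen and covers listed regions only. How much of the excess comes from shallow coverage with low levels therefore stays open. Chance sampling of few reads would move a region either way alike if the listing criteria favoured no direction. In the 90 regions with a depth of at least 20 in both libraries, 65.6% were higher (54.8 to 75.3). That test was chosen after its value had been seen and covers listed regions only, so it cannot exclude chance sampling. It replaced an earlier test, also written after the table had been seen, on regions with a p below 0.05 with reads as the unit, which could not decide, since it left 2 regions (2 of 2 higher, exact 95% interval 15.8 to 100). The stated conversion of non-CpG cytosines was above 99%, and no listed region differed by less than 10 points. A conversion failure as small as that stated, spread evenly over a library, would not give differences of this size. Conversion within single regions was not examined here, so incomplete conversion in some of them is not excluded. Also open and untested are another difference in library preparation, a difference between the animals other than the diet, and the diet itself, since each group had 1 library. A prediction about the animals was written and dropped, because it needs further libraries. The regions left out of the table, which could show whether the whole methylome moved, were not analysed here.

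Regions at imprinted genes may differ because few reads sample the methylated and unmethylated parental alleles unevenly. The levels at Magel2, Nnat with Blcap, Plagl1 and Gnas lay between 26.4% and 61.7% in both libraries, as a mixture of alleles could give. Some regions at genes outside the imprinted list also lay in this range, such as Otx1 (27.8% and 58.2%), so the levels alone decide nothing. With reads as the unit 0 of the 4 regions had a p below 0.05 (Fisher's exact p = 0.145 to 0.488), and with 2 reads per unit of depth 1 did, Plagl1 (Fisher's exact p = 0.0231). This test too was chosen after the data were seen. The number of reads per region is not in the table, so the explanation cannot be told apart from a change in methylation at these genes.

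If the differences covered wider domains, neighbouring regions would share a direction. Of 14 pairs of regions with a gap of 300 bp to 10 kb, 8 had the same direction, against a mean of 8.52 when directions were permuted (one-sided permutation p = 0.673). The pairs come from few genes, mainly Mn1, Bcor and Fignl2, and overlap within a gene. The prediction was written before the test, but the rule that at least 30 pairs are needed to decide was added after its p was seen, so the question stays open. Within Mn1, regions 698 bp apart differed by 14.5 and -10.5 points, and within Bcor, regions 646 bp apart by 10.2 and -11.3 points.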
